A study of Mus musculus with 2 samples.

How the data were processed

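The data were 2 Affymetrix Mouse430_2 arrays of MEF RNA, 1 from wildtype and 1 from Malat1 knockout mice, with the groups taken from the genotype in the labels. Per the labels' protocols, the cells came from embryos at day 13.5 on a C57BL/6 background and were cultured for 2 weeks, total RNA was extracted with Trizol, and biotin-labelled RNA was made from 100 ng of total RNA with a 3′ in vitro transcription kit. The authors deposited 1 value per probe set and array, which were taken here as log2 signals. That scale is inferred from the range of the values, 2.09 to 14.71, because the summarization and normalization methods and their software are not given in the sources used here. The sorted values of the arrays differed by up to 0.133, so the arrays did not share one distribution.

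The arrays held 45037 probe sets besides 64 controls. Gene names came from a table of the platform's annotation, in which 34958 probe sets had 1 gene symbol, 932 had several and 9160 non-control probe sets had none. The probe sets with 1 symbol include 13 controls, and 2 genes, Actb and Gapdh, are represented by one of these. Of the probe sets with 1 symbol, 34754 had a gene identifier in the RefSeq gene table of mouse assembly GRCm38.p6, and no symbol changed through it. Probe sets with several symbols or none were kept out of gene-level results. RefSeq was used for names, chromosome assignment and gene order alone, since the build behind the array is not given in the sources used here.

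A gene was represented by the probe set with the highest mean of both arrays. A probe set counted as measured on an array at or above that array's median over non-control probe sets (5.39 for the wildtype, 5.44 for the knockout), a convention in place of a detection call. Of 18195 genes, 11295 were measured on both arrays, 186 on the wildtype array alone, 414 on the knockout array alone and 6300 on neither. For a gene measured on 1 array, the ratio is a bound, the brighter signal against the other array's floor, and is written as at least that many fold. The median difference of measured probe sets, knockout minus wildtype, was -0.06, under the limit of 0.1 set for recentring, so the values were used as deposited. The difference had an SD of 0.24 across genes and Pearson's r between the arrays was 0.991 across genes, which are not independent replicates. The pooled SD of the difference between probe sets of one gene was 0.197.

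Control probe sets described the arrays. All 18 probe sets for hybridization spike-ins were lower on the knockout array, with a median of -0.23 and under the other 3 scalings as well. The 27 probe sets for Bacillus controls were near the floor or below it, at 5.58 at most, with a median of 0.13. The 3 probe sets for 18S ribosomal RNA were 0.47 to 0.67 higher on the knockout array, under the other scalings too. The signal at the 3′ end minus that at the 5′ end was 0.139 and 0.110 for Actb and -0.165 and -0.180 for Gapdh, on the wildtype and knockout array.

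No paired analysis was possible because each genotype has 1 array. With 1 array per group no p-value was computed across genes, and counts of genes used a fixed size of 2-fold. For 30 gene lists written before the data were examined, the median difference of the measured members was set against 10000 random lists of the same size drawn from 20 bins of mean expression, and lists with under 5 measured members have no such value, except in the later test of 4 X-linked genes. In the lists, 2 names matched no gene. The genes named are every Malat1 probe set and measured neighbour, the 12 genes with the largest difference in each direction, the 4 genes with the largest bound in each direction, and up to 4 members of each list with the largest difference. A few further genes (Dcn, Pecam1, Cdh5, Tie1, Krt18, Krt19, Mmp10, Il6, Eng, Ap2b1, Fgd6, Ddx3y, cornified envelope and p200 genes, and second probe sets) were named after the values were seen.

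The alternatives were setting the median difference to 0, quantile normalization, loess centring with a span of 0.3, no floor or a floor at the 75th or 40th percentile, adding 16 or 64 to linear values, the mean over measured probe sets, the median difference over all probe sets, leaving out probe sets ending in _x_at or _s_at, and sizes of 1.5-fold and 3-fold. Counts without X- and Y-linked genes, and counts of genes with support from a second probe set, were added after seeing the data. The calls were tested on simulated data for this 2-array comparison with 11411 genes. All 100 genes changed by 3-fold were called, 2% of 100 genes changed by 1.5-fold and 0 of 11211 unchanged genes. The simulated noise was the spread between probe sets of one gene (0.197), with no variation between cultures. Changed genes were drawn from brighter genes alone. The simulation therefore does not give the rate of false calls between cultures. Of 100 simulated lists without a shift 7 lay outside the central 95%, and all 100 lists shifted by 0.3 lay above it. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.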

Results

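Gene expression was measured in mouse embryonic fibroblasts (MEFs), the connective tissue cells that grow out of dissociated embryos, from wildtype mice and from mice lacking Malat1, a long noncoding RNA that is abundant in most cell types and is held in the nucleus at nuclear speckles, the bodies that store splicing factors. The embryos were taken at day 13.5 and the cells were kept in culture for 2 weeks without treatment. Total RNA from each genotype was hybridized to an Affymetrix Mouse430_2 array, giving 1 array for the wildtype and 1 for the knockout. On each array 34958 probe sets were paired with a single gene symbol, for 18195 genes. Log2 signals ran from 2.13 to 14.69 on the wildtype array and from 2.09 to 14.71 on the knockout array. With 1 array per genotype no difference below has a replicate check, so none carries a p-value, and the number of arrays limits the precision.

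The arrays were compared first for Malat1 itself, as a check of the labels. Malat1 RNA was high in the wildtype array and below the floor (each array's median signal, 5.39 for the wildtype and 5.44 for the knockout) in the knockout array. The brightest of its 7 probe sets read 9.80 in the wildtype and 4.53 in the knockout, a signal at least 20.6-fold lower. The next brightest read 9.49 and 3.38, at least 16.6-fold lower. Another 4 Malat1 probe sets were also above the floor in the wildtype array alone, with bounds of at least 6.42-fold, 6.05-fold, 2.63-fold and 1.80-fold lower. The remaining one lay below the floor on both arrays, at 4.71 and 4.55. Which of these probes lie within the DNA altered in the knockout is not given in the sources used here.

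The genes next to Malat1 were compared because a change to the locus can reach its neighbours. Neat1, the long noncoding RNA around which paraspeckles form, lies 2 genes from Malat1 and was the neighbour with the largest difference. Its brighter probe set read 9.73 in the wildtype and 8.65 in the knockout, 2.11-fold lower, while a dimmer Neat1 probe set read 6.68 and 6.88, a difference of 0.19 the other way. The other 14 measured neighbours were within 1.5-fold. Tigd3 was 0.48 log2 units higher in the knockout, Slc25a45 0.39 higher and Kcnk7 0.37 higher, and Rela, a subunit of the transcription factor NF-kappaB, differed by -0.09. Pola2, a subunit of DNA polymerase alpha, differed by -0.31, Ehbp1l1 by -0.30, Map3k11 by -0.24, Pcnx3 by -0.23, Cdc42ep2 by -0.16 and Sipa1 by -0.02. Capn1, a calcium-dependent protease, differed by 0.21, Frmd8 by 0.17, Ltbp3 by 0.03 and Dpf2 by 0.01. The median over the 15 measured neighbours was -0.02, a sign that turned under each of 3 other scalings of the arrays, and 77.28% of 10000 random gene lists matched on expression had a lower median.

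Transcripts of the sex chromosomes were among the largest differences between the arrays. Xist, the RNA that coats the inactive X chromosome of female cells, was below the floor in the wildtype array (4.50) and reached 11.49 in the knockout array, at least 68.5-fold higher, and its other 2 probe sets were above the floor in the knockout alone as well. The Y-linked genes Eif2s3y, Uty and Kdm5d were measured in the wildtype array alone. Eif2s3y, which encodes a translation initiation factor subunit, read 8.57 and 2.81, at least 8.77-fold lower in the knockout. Uty was at least 4.36-fold lower and Kdm5d, a histone demethylase, at least 4.01-fold lower. The X-linked genes Eif2s3x, Kdm6a, Kdm5c and Ddx3x, which escape X inactivation, were all higher in the knockout array, by 0.59, 0.32, 0.31 and 0.09 log2 units, with a median of 0.31. Sex-linked transcripts therefore separate the arrays in the same way as the genotype label.

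**Figure D1:**
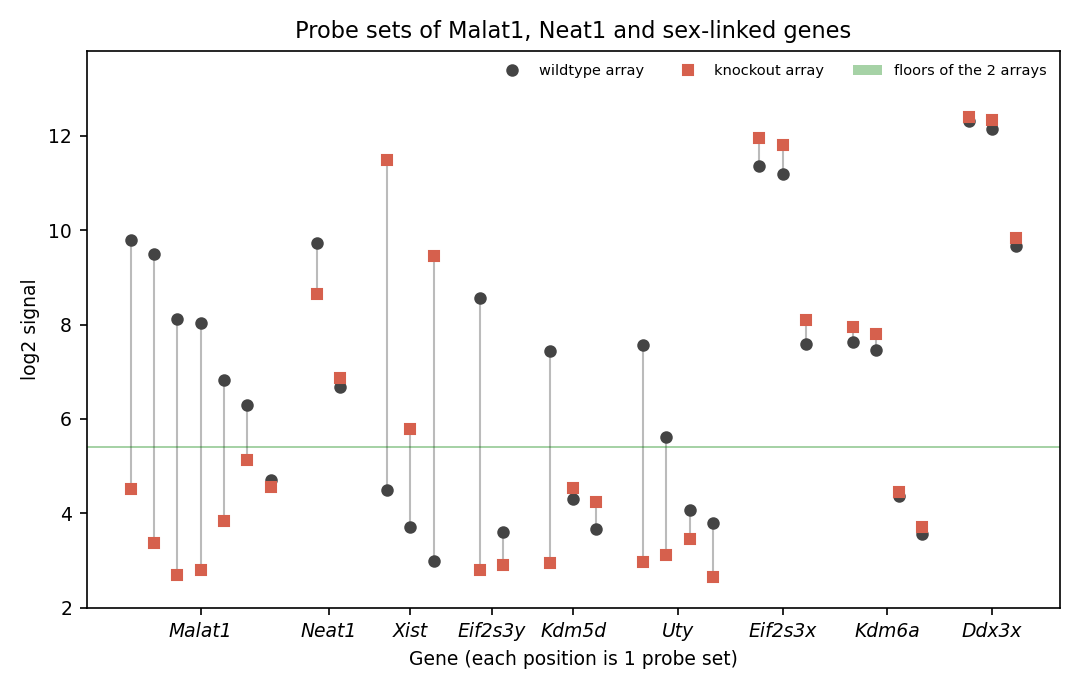
Log2 signal (y axis) of every probe set of Malat1, Neat1 and 7 sex-linked genes (x axis), with circles for the wildtype array, squares for the knockout array and a band for the floors of the 2 arrays. The brightest probe sets of Malat1, Eif2s3y, Kdm5d and Uty lie above the band in the wildtype array alone and that of Xist in the knockout array alone, at 4.50 and 11.49.

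The rest of the transcriptome was compared over the 11295 genes measured on both arrays. Most genes had similar signals, with 97.6% within 1.5-fold. The gene lower in the knockout array by the largest ratio was Ntn4, a netrin found in basement membranes, at 9.91 in the wildtype and 7.08 in the knockout (7.08-fold). The gene higher by the largest ratio was Tmem87a, a membrane protein, at 6.30 and 8.40 (4.29-fold). The 2-fold mark was passed by 8 genes higher and 30 genes lower in the knockout array, the 1.5-fold mark by 94 and 182, and the 3-fold mark by 1 and 3. Another 2 genes higher and 8 lower were measured on 1 array alone with a bound of at least 2-fold, among them Malat1, Xist and the 3 Y-linked genes. The split depended on scaling, with 12 higher and 22 lower after quantile normalization and 11 and 23 after loess centring, so that the lower genes made up 64.7% and 67.6% of the 2-fold genes in place of 78.9%.

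Among genes higher in the knockout array, Emcn, the mucin-like endomucin of blood vessel linings, was 1.47 log2 units higher (2.77-fold) and Rgs5, a regulator of G protein signalling typical of pericytes, 0.98 higher, with its other 3 measured probe sets also higher. Lce1h and Lce1i, late cornified envelope proteins of the skin surface, were 1.16 and 0.89 higher, and Cldn4, a claudin of epithelial tight junctions, was 1.13 higher. Slco4a1, an organic anion transporter, was 1.34 higher, with its second probe set at 6.37 and 7.58. Tph1, the first enzyme of serotonin synthesis, was 1.02 higher, Bex1 1.01 higher, Crim1 1.01 higher, Tmem267 0.99 higher and Serpinb2, an inhibitor of plasminogen activators, 0.95 higher. The only Tph1 probe set read 5.49 in the wildtype, just above the floor, and a second Crim1 probe set was 0.50 higher. The Lce1h and Lce1i signals come from probe sets of a type that can pick up related transcripts. Abhd1, Atp10d and Lrrc3b were measured in the knockout array alone, at least 2.17-fold, 1.92-fold and 1.81-fold higher, from wildtype signals just under the floor.

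Genes lower in the knockout array included secreted factors and a cell-cycle inhibitor locus. Cdkn2a, which encodes inhibitors of the cell cycle that accumulate as fibroblasts are passaged, was 2.67-fold lower, at 8.45 and 7.03. Cxcl5, a chemokine that attracts neutrophils, was 2.99-fold lower, Mdk, the heparin-binding growth factor midkine, 2.79-fold lower, and the matrix-associated proteins Coch and Ccn5 2.82-fold and 2.76-fold lower. Arrdc3, an arrestin domain protein, was 2.91-fold lower, Taf15, an RNA-binding protein, 2.90-fold lower, and Nnmt, which methylates nicotinamide, 2.65-fold lower. Ifi202b, a member of the p200 family of interferon-inducible genes, was 2.78-fold lower, and the gene model Gm6958 4.25-fold lower, with both Gm6958 probe sets lower. Paip1, which binds the poly(A)-binding protein in translation, was 3.15-fold lower at its brightest probe set, and its other measured probe sets disagreed, differing by -1.79 and 0.26. The second Ntn4 probe set read 5.76 and 5.48, a much smaller difference than the first.

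Probe sets of one gene gave a limited check within these arrays. Of 15 genes past the 2-fold mark with another measured probe set, 12 (80%) had one with the same sign and 7 (46.7%) had one at least 1.5-fold different in the same direction, against 73.2% and 4.18% of all 4883 genes with several measured probe sets. Since 97.6% of measured genes were within 1.5-fold, few had such a difference to repeat, so the 4.18% is a weak reference. A gene counted if any of its other measured probe sets agreed, even where another went the other way, as for Paip1. Probe sets of one gene share an RNA sample and are not replicates.

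**Figure D2:**
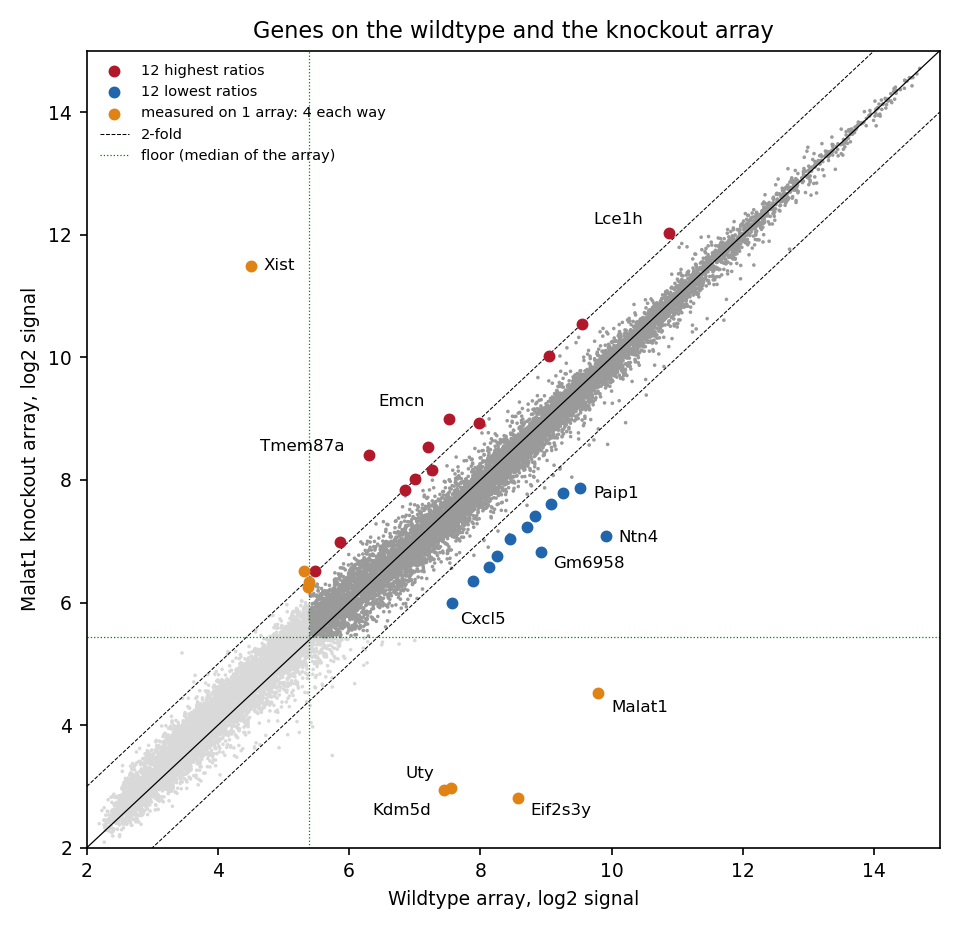
Log2 signal of each gene on the wildtype array (x axis) against the knockout array (y axis), with the genes of largest ratio in each direction coloured, dashed lines at 2-fold and dotted lines at the floors. Most genes lie on the diagonal (97.6% of measured genes within 1.5-fold), and Xist, Malat1 and 3 Y-linked genes stand farthest from it.

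Gene lists fixed before the data were examined were then compared, each by the median log2 difference of its measured members and by the share of 10000 expression-matched random lists with a lower median. This share describes these 2 arrays, and random lists can be too narrow a reference for genes that vary together. Of 28 lists with at least 5 measured members, 10 lay outside the central 95% of random lists, 7 below and 3 above. The number expected would be 1.4 if genes within a list varied as independently as those of random lists.

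Matrix genes were lower in the knockout array as a group. Of 29 measured genes for fibrillar collagens and other matrix proteins, 25 were lower in the knockout array, with a median of -0.19, and none of the 10000 random lists was as low. Col1a1, the main chain of type I collagen, and Col6a1, Col6a3 and Col6a2, the chains of microfibrillar collagen VI, were lower by 1.93-fold, 1.93-fold, 1.77-fold and 1.76-fold, and a second Col1a1 probe set read 12.07 and 11.74. Dcn, the collagen-binding proteoglycan decorin, was 0.74 log2 units higher. Under the other scalings 23 or 24 of the 29 stayed lower.

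Splicing factors of nuclear speckles, where Malat1 resides, were slightly lower as a group. Of 31 measured members 28 were lower in the knockout array, with a median of -0.11, and 0.72% of random lists were lower. No member passed 1.5-fold, and the median over all measured genes was -0.05 and that of the 18 hybridization spike-in probe sets, lower under every scaling, -0.23. Srsf10, a splicing factor of the SR family, differed by -0.38, Srsf4 by -0.29, the splicing kinase Clk2 by -0.27 and Luc7l3 by -0.25. With the median difference of all measured probe sets set to 0, 19 of the 31 stayed lower and the median became -0.05. The list for paraspeckle components, which contains Neat1 and Taf15, had a median of -0.10 over 16 measured genes, inside the range of random lists (8.67% lower), with Pspc1 at -0.32 and Cpsf6 at -0.21. With the median over all probe sets of a gene it lay outside (1.09% lower).

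Genes of fibroblast senescence and its secretory phenotype had a median of -0.21 over 19 measured genes, with 12 lower and 7 higher in the knockout array and 0.16% of random lists lower. Their median was -0.15 to -0.12 under the other scalings. Besides Cxcl5 and Cdkn2a, the genes at least 1.5-fold lower were the chemokine Ccl7 at -0.73 and Igfbp5, an insulin-like growth factor binding protein, at -0.83. A second Igfbp5 probe set differed by 0.23 the other way, and the matrix metalloproteinase Mmp10 and the cytokine Il6 were higher by 0.49 and 0.39. Mitosis genes had a median of -0.17 over 24 measured members (1.15% of random lists lower), with the kinases Plk1, Bub1 and Ttk at -0.49, -0.39 and -0.35 and the motor protein Kif11 at -0.41. Under the other scalings the mitosis median was -0.10 to -0.08, with 17 of the 24 lower. No mitosis gene passed 1.5-fold, and the list came back inside the range of random lists with the floor at the 75th percentile (12.01% lower) and with the median over all probe sets of a gene (4.57% lower). Genes of DNA replication and S phase were inside the range, with a median of -0.09 over 23 genes (19.92% of random lists lower) that turned to 0.01 after quantile normalization, Cdc6 at -0.36 and the transcription factor E2f1 at 0.27.

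Oxidative stress and metallothionein genes had a median of -0.23 over 13 measured members, with 0.29% of random lists lower. Nqo1 and Hmox1, both targets of the stress-responsive factor Nrf2, differed by -0.65 and -0.63, Mt2 by -0.34 and Gsr, glutathione reductase, by -0.34. Hypoxia and glycolysis genes had a median of -0.14 over 22 members (0.82% lower), which was -0.09 to -0.08 under the other scalings. Pfkl, a phosphofructokinase, was 1.84-fold lower at its brightest probe set and its other 2 probe sets differed by -0.27 and -0.17, while Ndrg1, Bnip3 and Pdk1 differed by -0.50, -0.49 and -0.36. The hypoxia call was lost with the mean over measured probe sets (11.57% lower) and with the median over all probe sets (8.35% lower).

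Markers of other cell types that a MEF culture can hold differed in both directions. Epithelial genes were higher in the knockout array, with a median of 0.34 over 10 measured genes that no random list reached. Cldn4, Perp, a desmosome protein also on the list of p53 targets, and Cldn3 were higher by 1.13, 0.74 and 0.54 log2 units, while Sfn, an epithelial 14-3-3 protein, was 0.62 lower (-0.62). Cldn4 has 1 probe set, which read 5.86 in the wildtype, near the floor, and a second measured Cldn3 probe set differed by 0.10. Endothelial genes had a median of 0.41 over 5 measured genes (99.99% of random lists lower), with Emcn and the growth factor receptors Kdr and Flt1 (0.47 and 0.41) at or above it and Egfl7 (0.11) and Eng (0.03) near 0. Another Egfl7 probe set differed by -0.25, and the other Flt1 probe sets by 0.10 to 0.21. The endothelial genes Pecam1, Cdh5 and Tie1 were below the floor on both arrays, and the call was lost without a floor (76.85% lower) and with the floor at the 40th percentile (86.72% lower). Genes of neurons, glia and neural crest had a median of 0.17 over 10 genes (98.57% lower), with the growth cone protein Gap43 at 0.86, Ngfr at 0.48, Sox10 at 0.33 and Stmn2 at -0.34.

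Macrophage and other leukocyte genes had a median of -0.27 over 19 measured genes that no random list matched, with 15 lower in the knockout array. The mannose receptor gene Mrc1, Aif1, the lysozyme gene Lyz2 and Lcp1 differed by -0.59, -0.47, -0.46 and -0.42, and a second Lcp1 probe set by 0.42 the other way. Lyz2 read 11.20 in the wildtype and 10.74 in the knockout. This call was lost with the mean over measured probe sets (13.31% lower), without probe sets that can pick up related transcripts (18.24% lower) and with the median over all probe sets of a gene (7.33% lower).

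The remaining lists lay inside the range of random lists with the values as deposited. Muscle and fat markers came closest to its ends among cell types. Skeletal muscle genes had a median of -0.20 over 11 genes (3.99% of random lists lower), with the myosin light chains Mylpf at -0.60 and Myl1 at -0.47, while adipocyte genes had a median of 0.28 over 6 genes (97.11% lower), with the glucose transporter Slc2a4 at 0.61 and the lipase Lpl at 0.45. Of the muscle genes 7 were lower and 4 higher in the knockout array, the higher ones including Des at 0.44 and Ckm at 0.32. Mitochondrial respiratory chain genes had a median of 0.06 over 23 genes (97.47% lower), with 19 of them higher in the knockout array, among them Ndufb2 and Uqcrb at 0.24 and 0.24, and the list was outside the range in 4 of 11 alternatives (97.53% to 99.31% lower). Imprinted genes had a median of 0.04 over 17 genes (91.54% lower), and Rian, a maternally expressed noncoding RNA, was 2.15-fold lower, with Meg3 and Mirg from the same gene cluster at -0.33 and -0.26. Other measured probe sets differed by -1.04 to -0.08 for Rian, -0.63 to 0.14 for Meg3 and -0.93 for Mirg. The medians were -0.09 for interferon-stimulated genes (13 genes, 13.66% lower, Irf9 at -0.53), -0.13 for positional transcription factors other than Hox (21 genes, 10.19% lower, Tbx4 at -0.50) and -0.10 for cartilage and bone (6 genes, 14.73% lower, Sox9 at -0.34). The interferon list was outside the range without a floor (0.72% lower) and with the floor at the 40th percentile (1.74%), and the positional list without a floor (0.89%) and at the 75th percentile (0.62%). The imprinted list was outside it without a floor (98.15%) and the adipocyte list with the mean over measured probe sets (97.51%). Of the erythroid genes, 2 were measured, Rhd at 0.28 and Tfrc, the transferrin receptor, at 0.09, too few for a comparison with random lists.

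For the following lists the sign of the median turned under at least 1 of the 3 other scalings. The p53 targets had a median of -0.05 (21 genes, 43.41% lower), with the growth arrest gene Gadd45a at -0.53, and the unfolded protein response and heat shock list had -0.03 (20 genes, 33.83% lower), with Trib3 at -0.58. Cholesterol synthesis genes had a median of -0.08 (17 genes, 43.72% lower), with the enzyme Lss at -0.46, and cytosolic ribosomal proteins 0.01 (18 genes, 56.69% lower). Contractile and myofibroblast genes had a median of 0.02 (17 genes, 69.51% lower), with the intermediate filament gene Des at 0.44, and serum immediate early genes -0.02 (19 genes, 85.02% lower), with Klf4 at -0.53. Hox genes had a median of -0.02 (24 genes, 84.79% lower), with Hoxa5 at 0.48 and a place outside the range with the floor at the 75th percentile (99.16% lower), and synapse genes -0.07 (7 genes, 42.56% lower), with the adhesion molecule Cadm1 at 0.55. The other Cadm1 probe sets differed by 0.08 to 0.22.

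**Figure D3:**
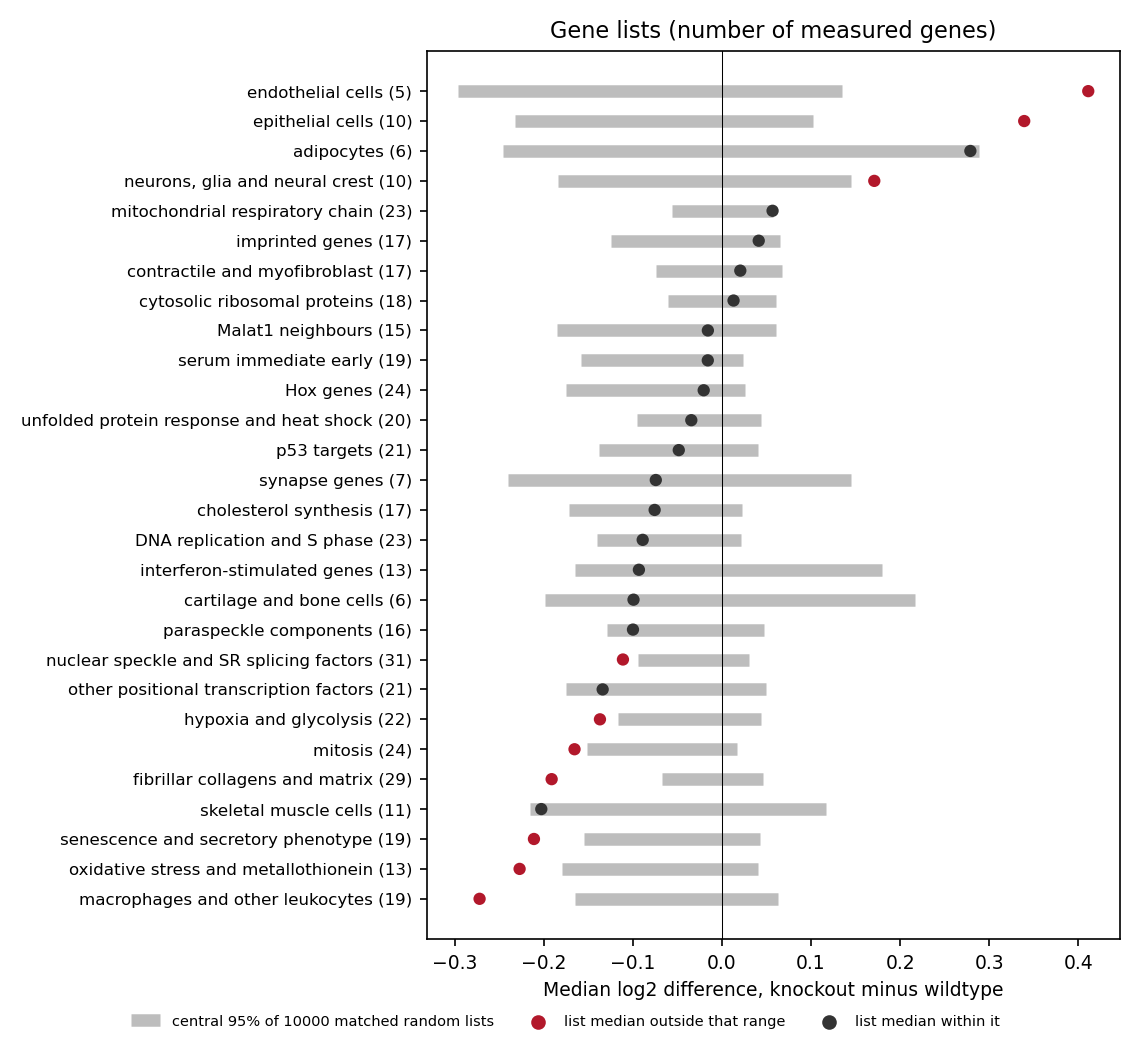
Median log2 difference, knockout minus wildtype (x axis), of each gene list with at least 5 measured genes (y axis, number measured in parentheses), as points over bars for the central 95% of 10000 expression-matched random lists. The 10 red points lie outside their bars, from -0.27 for macrophages and other leukocytes to 0.41 for endothelial cells.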

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

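All tests of explanations in this part were chosen after the results were seen.

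Probe sets without a single gene symbol were not part of the comparison of genes, and some of them differed strongly. Of 10092 such probe sets, 2432 were measured on both arrays, and 1 was at least 2-fold higher and 12 at least 2-fold lower in the knockout array. The largest bounds were those of a probe set that read 10.23 in the wildtype and was below the floor in the knockout, at least 27.7-fold lower (a bound of -4.79 on the log2 scale), and of another that read 5.34 and 7.32, at least 3.80-fold higher (1.93). Neither has a gene name in the annotation used here. Other probe sets without a gene name read 8.35 and 3.28, and 7.89 and 2.99, in the wildtype and knockout. Like the probe set at 10.23, they were measured in the wildtype array alone, as the Y-linked genes were. Of the 9 genes on the sex-linked list, 8 had a probe set with 1 symbol, and Ddx3y had none. Whether these probe sets measure a sex-linked transcript cannot be told here.

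Xist was measured in the knockout array alone, and Eif2s3y, Uty and Kdm5d in the wildtype array alone, although the labels state no sex. An exchange of the labels is argued against by Malat1, whose largest bound is -4.36 in the array labelled knockout, with 6 of its probe sets lower there and 0 higher. A candidate explanation is that the cultures came from embryos of different sex, since the 4 X-linked genes that escape inactivation had a median difference of 0.31, at the 99.95th percentile of matched random lists of 4 genes, fewer than the 5 asked of other lists. Of the 38 genes measured on both arrays and past the 2-fold mark, which leave out Xist and the 3 Y-linked genes, 37 lie outside the X and Y chromosomes, and for these a sex difference cannot be told apart from the genotype, because each genotype has 1 array and each array 1 pattern of sex-linked transcripts. The genotype therefore stays an open and untested explanation for them.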

How the results depend on the processing

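The counts of genes with support from a second probe set, and those without X- and Y-linked genes, were chosen after seeing the data, and the other alternatives were fixed before. The number of genes at least 2-fold higher in the knockout array (8 as reported) and lower (30), bounds not counted, followed from the size and the floor. It was 94 and 182 at 1.5-fold, 1 and 3 at 3-fold, 15 and 51 without a floor, and 2 and 13 with the floor at the 75th percentile. Adding 64 to linear values left 4 and 17, and adding 16 left 4 higher. The median over all probe sets of a gene gave 19 lower, 18 of them shared with the 30, and support from a second probe set was found for 1 higher and 6 lower. The counts at other sizes, floors and added values follow from the construction of those settings. Only 15 of the 38 genes past 2-fold had another measured probe set, so the count with such support was lower by construction. The median over all probe sets also takes in probe sets below the floor, and the cause of its changes was not tested. Without X- and Y-linked genes 7 and 30 remained. The Malat1 bound of -4.36 was -5.27 without a floor, -4.98 and -2.18 with floors at the 40th and 75th percentiles, -3.93 and -3.15 with 16 and 64 added, and -5.23 as a median over probe sets, lower in the knockout array each time.

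The matrix and nuclear speckle lists kept their side of the random range in 11 of 11 alternatives, with medians from -0.23 to -0.13 and from -0.17 to -0.05. The random lists were drawn from the same rescaled values, so setting the median difference to 0 could not change the side of any list. No list changed side under quantile normalization or loess centring either, where the matched random lists were rescaled as well. Over all lists, 279 of 300 alternative values kept their side, 9 came inside the range and 12 went outside it, and none of the lists outside the range changed sign. The cause of these changes was not tested. Of 1520 alternative values of named genes 88 moved by more than the spread between probe sets of one gene. None of the named genes past 2-fold changed sign, and 11 named genes changed sign under some alternative, of which Igfbp5 was the only one at least 1.5-fold different as reported. Signals near the floor limit the comparison, because 6300 genes were below it on both arrays and a bound there depends on where the floor is set.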

Other observations

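The tests in this part were chosen after the results were seen, except the test of the genes around Malat1, which was set before its result.

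Genes of the cornified envelope, the protein shell of the outer skin layer, stood out among the genes higher in the knockout array. In a list of such genes chosen after seeing the data, 16 of 39 were measured, 13 were higher in the knockout array and 8 at least 1.5-fold higher. Sprr1a and Sprr2k, small proline-rich envelope proteins, were higher by 0.87 and 0.70 log2 units, Lor, the envelope protein loricrin, by 0.69 and Sprr3 by 0.68, while Sbsn differed by -0.53 and Flg and the keratin Krt1 were below the floor on both arrays. With the 4 members among the 100 most different genes left out, the remaining 12 had a median of 0.48, above all 10000 matched random lists. This comparison cannot test a shift across the group. The list was chosen from these same arrays, and random lists hold unrelated genes. The probe sets of 6 of the 16 can pick up related transcripts, so these members are not independent.

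The p200 family of interferon-inducible genes, also chosen after seeing the data, had 2 of 8 members measured on both arrays. Ifi202b differed by -1.48 and Ifi203 by 0.22, and below the floor Ifi204 read 4.93 and 3.63 and Mndal 3.65 and 4.81 in the wildtype and knockout. Of probe sets paired with several symbols, one for members of the family was at least 3.60-fold higher in the knockout array and another 3.31-fold lower.

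Some of the most different genes lie close to each other in the genome, such as Taf15 with Ap2b1 (-1.54 and -1.35) and Ntn4 with Fgd6 (-2.82 and -0.84). Among the 100 genes with the largest differences, 15 pairs lay within 5 measured genes of each other, against 4.40 expected from 10000 permutations of gene positions, which never gave more than 14 (permutation p = 0.0001, the smallest they can give). Gene families with shared probes or regulation remain open as the source, because 8 pairs were left without family pairs when Lce and Sprr genes counted as one family (permutation p = 0.0733), a grouping made after 11 pairs had been left with them apart (permutation p = 0.0056). DNA segments of another mouse strain, for which probe sets of one gene should disagree more often, also remain open, since 3 of 5 such genes in the pairs and 9 of 34 others had probe sets over 1 log2 unit apart (one-sided Fisher's exact p = 0.159). For DNA carried along with the knockout allele, the 99 measured genes around Malat1, with Neat1 left out, had a median absolute difference of 0.167, at the 93.3rd percentile of windows of that many genes, and 0 of them were 2-fold different, which decides neither way.

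Matrix genes were lower and epithelial genes higher in the knockout array. If the share of fibroblasts alone were lower, markers of every other cell type would be higher, but the macrophage genes were lower. The epithelial median exceeded the macrophage median by 0.611. The macrophage list came inside the random range under 3 alternatives, with medians no higher than -0.11. These values cannot decide on a lower share of fibroblasts, because the share of macrophages may differ as well. Scaling of the arrays by signal level is argued against by the matrix median relative to all measured genes. It stayed at -0.19 after loess centring and was -0.14 with values as deposited. More epithelial cells in the knockout culture may account for the epithelial part and stay open, since 7 of 19 epithelial genes were below the floor in the knockout array, 3 of 10 measured ones were lower there, and the list genes with the highest signals there, Krt19, Perp and Krt18, read 8.66, 8.37 and 8.34 against 8.53, 7.63 and 7.87 in the wildtype. The genotype and the sex of the embryos remain open as well and were not tested apart.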
